A study of Homo sapiens with 8 samples.

How the data were processed

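Total RNA of HCT116 cells was reverse transcribed with random hexamers and sequenced at a commercial facility, per the labels' protocols, which leave open whether the libraries kept strand. Per the submitters' processing notes the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, named without a role for each step; the strand setting of the counting is not given in the sources used here. The deposited table holds FPKM (fragments relative to exon length and library size) of 58735 genes in 8 libraries, as made by the authors. All 58735 identifiers, names, starts and ends match GENCODE 29 on GRCh38, and the gene lengths equal the union of annotated exons for all 58735, so coordinates are given in that build. Groups were taken from the labels: control shRNA at 20 mM and at 0 mM glucose for 24 h, MAPKAPK2 shRNA 1 and MAPKAPK2 shRNA 2 at 20 mM, with 2 libraries each.

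Each FPKM multiplied by the gene length is a whole multiple of 1 step per library, within 0.001 of a step and in proportion more for large values. This held for 100% of values and gave back the reads per gene. They sum to 14252316 to 19975449 per library, and the sum of reads was 0.932 to 1.05 times the library size that the authors divided by. How that size was defined is not given in the sources used here. Counting error was expressed as exact 95% Poisson intervals of the recovered reads, and 0 reads as an upper limit of 3 reads; both cover counting error only.

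The planned test used log2(FPKM + 1) and the 16239 genes with an FPKM of at least 1 in at least 2 libraries, 11446 of them protein-coding. Fold changes on this scale understate the change of genes with low FPKM. One limma model (limma 3.58.1 in R 4.3.3, eBayes with an intensity trend) with 4 group means and 4 residual degrees of freedom gave contrasts for 0 against 20 mM glucose, the mean of both MAPKAPK2 shRNAs against control, each shRNA alone, and shRNA 2 against shRNA 1. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and the knockdown contrast also needed the same sign for both shRNAs. Overlaps of calls were set beside those of independent lists, and covariances of fold changes beside 200 simulations of unchanged groups that share the controls. Groups, tests, the filter, the rule for named genes and the lists below were fixed before the data were examined.

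After the data were seen, a limma voom fit to the recovered reads was added, with the authors' library sizes and the same 16239 genes; it is called the read-based fit. It carries the named glucose genes, because the planned fit called 0 there. Fits to protein-coding genes only, and other settings of the read-based glucose fit, were added at the same point. A split of the 20 mM controls, with a different library for each comparison, was added last.

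A total of 34 gene lists with 892 members covered stress responses, metabolism, the cell cycle, MK2 and p38 signalling, translation, epithelial identity and other cell types, and 32 had at least 5 tested members. They were tested with limma camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists. Calls by fry, which asks only whether a list's own genes move one way, numbered 11 for glucose and 15 for the knockdown. Members were counted past the all-gene threshold and when adjusted over the list alone.

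The rule for named genes took, for glucose and for the knockdown, up to 10 genes with the largest rise and 10 with the largest fall among protein-coding genes past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the compared libraries. For the difference between shRNAs it took 5 in each direction, for each list up to 4 members with the smallest p, and for the overlap of both comparisons the 5 with the largest smaller change. MAPKAPK2, MAPKAPK3, MAPK14, HSPB1, ZFP36, TXNIP, ARRDC4, HSPA5, DDIT3 and ASNS were always named. For glucose the rule was applied to the read-based fit, and DHRS2 was named for the overlap. Some genes that the rule covers are not reported here.

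Annotated exons were searched for overlaps. Reads of antisense genes cannot be assigned without strand, and strand does not separate genes that overlap on the same strand. Of 115 named genes 46 overlap another gene's exons and 8 by over 20% of their exon bases: ARG2, ASNS, DDIT3, DDIT4, IER3, NGFR, PLAU and TYMS. Their levels, and those of genes with near-identical copies such as HMGN2, KRT81, RPL8 and the metallothioneins, are uncertain to that extent.

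The tests were tested on simulated data, in which reads for the real genes were drawn with known changes. Genes were drawn independently and with the same dispersion (0.00997) for all. The spread of the real data differs between genes and groups, so the rates below need not hold there. For the glucose contrast (15405 genes) the planned fit recovered 11.9% of 1.5-fold, 53.0% of 2-fold and 84.8% of 4-fold changes, and the read-based fit 43.3%, 84.8% and 86.4%, with 6.60% and 7.14% false calls. For the knockdown contrast (15457 genes) the planned fit recovered 22.4%, 59.1% and 87.9% and the read-based fit 62.7%, 83.3% and 97.0%, with 3.45% and 7.22% false calls. Alternatives were another pseudocount, stricter and absent filters on low values, median ratio rescaling, quantile normalization, eBayes without a trend, only the groups compared, the replicate number as a block and leaving out each library in turn. Tables were read with Python 3.11.15, and figures were drawn with matplotlib 3.10.9.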

Results

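RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, in 8 libraries that form 4 groups of 2. In 2 groups the cells expressed a control shRNA (short hairpin RNA) and were kept for 24 h in medium with 20 mM or 0 mM glucose. The other 2 groups expressed shRNA 1 or shRNA 2 against MAPKAPK2, the gene of MK2, a kinase that p38 MAP kinases activate in stress signalling. These cells were kept at 20 mM glucose for a time not given in the sources used here. The libraries held 14252316 to 19975449 reads in genes, and 13821 to 14611 genes per library reached an FPKM of 1. Pearson's r of log2(FPKM + 1) across genes was 0.962 to 0.970 between the libraries of a group, 0.958 to 0.970 between control libraries at 20 and 0 mM, and 0.925 to 0.941 between control and MAPKAPK2 shRNA libraries; genes are not independent replicates. Between libraries with shRNA 1 and libraries with shRNA 2 it was 0.929 to 0.933. On the third principal component (11.4% of the variance) the second 0 mM control, at 32.4, and the second shRNA 2 library, at 18.4, stood apart from the others, at −16.7 to 0.964. The libraries of every group differed by more than sampling noise, with a chi-square per gene of 6.08 in the 20 mM controls, 11.6 in the 0 mM controls, 7.07 with shRNA 1 and 30.6 with shRNA 2. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

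MAPKAPK2 mRNA was low in all 4 libraries with a MAPKAPK2 shRNA and in none of the 4 control libraries. The gene (ENSG00000162889) lies on chromosome 1 from 206684944 to 206734283 in GRCh38. Its level was 16.4 and 16.2 FPKM in the controls at 20 mM and 17.9 and 18.9 FPKM in those at 0 mM. With shRNA 1 it was 2.77 and 2.54 FPKM, from 219 and 163 reads, a mean of 16.3% of the 20 mM controls. With shRNA 2 it was 0.982 and 0.800 FPKM, from 78 and 54 reads, a mean of 5.46%. Over both shRNAs the log2 fold change was −2.72 (SE 0.08, limma adjusted p = 5.9e-05), and shRNA 2 left less mRNA than shRNA 1, by a log2 fold change of −0.95. Glucose withdrawal gave 0.16 (SE 0.09, limma adjusted p = 0.699).

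**Figure D1:**
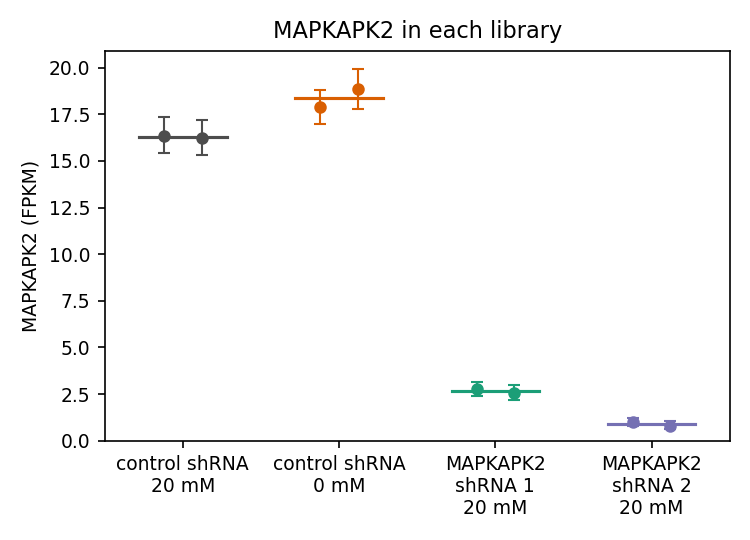
MAPKAPK2 level in FPKM (vertical axis) in each of the 8 libraries by group (horizontal axis), with points for libraries, error bars for the exact 95% Poisson interval of the reads (counting error only) and lines for group means. The control libraries lie between 16.2 and 18.9 FPKM and the MAPKAPK2 shRNA libraries between 0.800 and 2.77 FPKM.

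The first comparison asked how the cells respond to 24 h without glucose. Transcripts of the stress regulators DDIT3 (CHOP) and DDIT4 (REDD1) rose most among protein-coding genes past the read-based test. DDIT3 went from 4.67 FPKM ± 1.42 to 16.6 ± 1.73 (SD, n = 2 each) and DDIT4 from 9.38 ± 1.15 to 23.8 ± 1.64. The glucose transporter gene SLC2A3 rose from 12.4 ± 1.40 to 22.5 ± 1.91, and HSPA5, the ER chaperone BiP, from 226 ± 5.23 to 350 ± 48.1. ARRDC4, an arrestin gene that the glucose sensor MondoA activates, fell from 1.72 ± 0.136 to 0.371 ± 0.105. As groups, genes of the ATF4 stress response stood higher at 0 mM and genes of DNA replication lower. Genes of mitosis and heat shock stood lower too, by limma camera calls that were lost with an estimated correlation (adjusted p = 0.164 and 0.169).

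These genes come from a limma voom fit to reads recovered from the FPKM, a test added after the data were seen. It called 28 genes, 25 up and 3 down and including the pseudogenes NSFP1 and GTF2IP1, where the planned limma fit to log2(FPKM + 1) called 0, with 1421 of 16239 genes at an unadjusted p under 0.05 against 812 by chance and a lowest adjusted p of 0.0863. In the read-based fit the log2 fold change was 1.86 for DDIT3 (SE 0.23, limma adjusted p = 0.0128), 1.35 for DDIT4 (0.0290), 0.85 for SLC2A3 (0.0131), 0.63 for HSPA5 (0.0454) and −2.26 for ARRDC4 (0.0231). Of the exon bases of DDIT3, 27.2% overlap MARS on the opposite strand, and 41.2% of those of DDIT4 overlap DDIT4-AS1, so reads may be shared where the counting ignored strand; MARS itself had means of 35.0 and 35.9 FPKM. The count rests on single libraries: it was 0 without either 20 mM control, 6 or 1 without the first or second 0 mM control, 7 without either shRNA 1 library, and 196 or 194 without the first or second shRNA 2 library.

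Other risers were ABCC3, an export pump of organic anions (3.99 to 8.49 FPKM, read-based log2 fold change 1.09), the circadian factor DBP (3.32 to 6.74, 1.02), the metallothionein MT1E (77.1 to 155, 1.01), the uridine phosphorylase UPP1 (12.7 to 23.7, 0.90), the laminin chain LAMB3 (15.8 to 29.3, 0.90) and AHNAK2 (11.8 to 21.4, 0.85). KRT80 and KRT7, both keratins, had read-based log2 fold changes of 0.81 and 0.76, and the insulin receptor substrate IRS2 of 0.80. Besides ARRDC4 the fallers were GMNN, the replication licensing inhibitor geminin (20.97 to 12.4 FPKM, −0.76), and the dehydrogenase DHRS2 (2.66 to 1.33, −0.996). TXNIP, the best known MondoA target, had 0 reads in all 4 control libraries, which allows at most 0.0541 FPKM in any of these. Its highest library, the second with shRNA 2, was at 0.0857 FPKM, so TXNIP was not tested. The 8 tested MondoA and ChREBP targets were not called as a list by limma camera (median 0.01, mean −0.09, adjusted p = 0.629). They were called by fry (adjusted p = 0.0203), with 4 members above 0 and 4 below, and only ARRDC4 past the read-based test. The list was not tested without ARRDC4. Neither MAPKAPK3, MAPK14 (p38α), HSPB1 nor ZFP36 passed the test, with log2 fold changes of −0.10, −0.15, −0.30 and 0.09.

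Of 39 tested members of the ATF4 list, which holds amino acid and integrated stress genes, 35 stood above 0 (median log2 fold change 0.26). In the planned fit 0 passed over all genes and 8 rose when adjusted over the list alone, and in the read-based fit 5 rose, among them DDIT3, DDIT4, TRIB3 (12.1 to 21.3 FPKM), and PCK2 (6.55 to 11.7). ASNS, a classic ATF4 target, went from 1.31 to 1.92 FPKM without passing. Of its exon bases 44.6% overlap AC079781.5 on the same strand, so its level is uncertain. The list was called up by limma camera at adjusted p = 5.7e-13, and at adjusted p = 0.0498 with an estimated correlation. Of 22 hypoxia genes 19 stood above 0, and 5 rose when adjusted over the list alone (median 0.18, limma camera adjusted p = 1.8e-06, adjusted p = 0.238 with an estimated correlation). NDRG1 (11.96 to 20.0 FPKM) rose in the read-based fit. In the glycolysis list of 27, HK2 (8.03 to 13.5) and SLC2A3 rose in the read-based fit and 2 genes when adjusted over the list alone in the planned fit, and SLC2A1 went from 126 to 157 without passing (median 0.03, limma camera adjusted p = 0.0251, adjusted p = 0.630 with an estimated correlation), a call that held in 5 of 8 fits with a library left out. The median was 0.05 under quantile normalization and 0.01 to 0.07 without 1 library. The ER chaperone list of 33 held 17 members above 0 and 16 below, with HSPA5 and HERPUD1 (10.3 to 19.2) up in the read-based fit and 3 up when adjusted over the list alone. Its call (median 0.03, limma camera adjusted p = 0.0482, adjusted p = 0.608 with an estimated correlation) held in 1 of 8 fits with a library left out (medians −0.04 to 0.10) and was lost in the fit with the replicate number as a block (adjusted p = 0.0718).

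All 42 DNA replication genes were tested, and 40 stood below 0 (median −0.29). In the planned fit 0 passed over all genes and 21 fell when adjusted over the list alone, for example MCM4 from 56.5 to 40.9 FPKM, FEN1 from 62.9 to 45.8, GINS2 from 18.6 to 12.4 and MCM10 from 14.8 to 9.76. The list was called down at a limma camera adjusted p of 4.7e-16, and at adjusted p = 0.0462 with an estimated correlation. Of 35 mitosis genes 34 stood below 0 (median −0.38), and when adjusted over the list alone 19 fell and 1 rose. CCNA2 went from 44.4 to 32.6 FPKM, PLK1 from 34.1 to 24.8 and BUB1 from 21.7 to 15.5 (limma camera adjusted p = 4.7e-16, adjusted p = 0.164 with an estimated correlation). Of 21 heat shock genes 19 stood below 0 (median −0.23), with 3 down when adjusted over the list alone, and BAG3 went from 45.3 to 30.7, DNAJA1 from 108 to 74.9 and HSPH1 from 36.0 to 26.6 FPKM (limma camera adjusted p = 1.2e-06, adjusted p = 0.169 with an estimated correlation).

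In all, limma camera called 15 of 32 lists at 0 mM, 11 up and 4 down, of which the DNA replication and ATF4 lists held with an estimated correlation. Immediate-early genes were called up (median 0.19, 3 up when adjusted over the list alone), where DUSP5 went from 59.5 to 87.2 and DUSP4 from 45.5 to 62.3 FPKM, as were targets of ARE-binding proteins such as TTP (0.14, 2 up), YAP and SRF targets (0.15, 1 up) and p53 targets (0.10, 0 up). Their adjusted p with an estimated correlation was 0.203, 0.203, 0.293 and 0.171, and the YAP and SRF median was as low as 0.09 without 1 library. The secretory and glycan list was called down (−0.16, adjusted p = 0.462 with an estimated correlation), in 6 of 8 fits with a library left out (highest median −0.09). Mitochondrially encoded genes (0.23), ribosomal proteins (0.07) and epithelial genes (0.15) were called up, each in 6 of those 8 fits, with adjusted p = 0.646, 0.830 and 0.465 with an estimated correlation. Without 1 library the medians ran from 0.03 to 0.36 for mitochondrially encoded genes, from −0.005 to 0.18 for ribosomal proteins and down to 0.06 for epithelial genes. Under quantile normalization the mitochondrially encoded and ribosomal protein calls were lost (both medians 0.03, adjusted p = 0.429 and 0.487). The share of reads on mitochondrially encoded genes was 6.83% and 7.82% in the 20 mM controls and 7.28% and 8.72% at 0 mM. No other list was called by limma camera in the planned fit. Under quantile normalization it called cholesterol genes up (adjusted p = 0.0438). Besides the MondoA list, fry called 3 lists that limma camera did not, those of pentose phosphate (adjusted p = 0.0461), interferon-stimulated (0.0480) and ribosome biogenesis genes (0.0363).

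**Figure D2:**
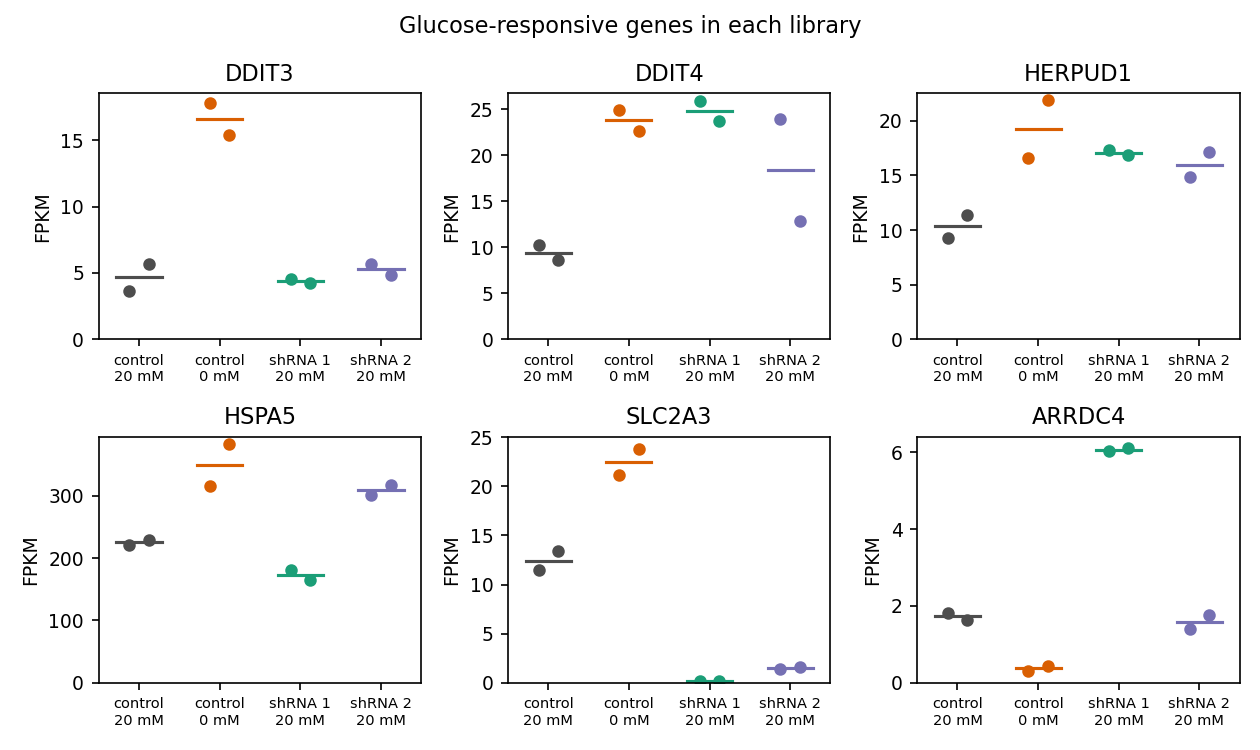
Levels in FPKM (vertical axes, from 0) of 6 glucose-responsive genes in each library by group (horizontal axes), with points for libraries and lines for group means. DDIT3 has a mean of 16.6 FPKM at 0 mM glucose and of 4.38 and 5.27 FPKM with the MAPKAPK2 shRNAs, while SLC2A3 has 22.5 FPKM at 0 mM and 0.173 and 1.495 FPKM with the shRNAs.

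The second comparison set the MAPKAPK2 shRNAs against control shRNA at 20 mM glucose. Cells with either shRNA had far less mRNA of the neuronal-type glucose transporter SLC2A3 and of the neurotrophin receptor NGFR. SLC2A3 was at 12.4 FPKM ± 1.40 in the controls, 0.173 ± 0.0254 with shRNA 1 and 1.495 ± 0.126 with shRNA 2 (SD, n = 2 each), and NGFR at 10.4 ± 1.34, 0.522 ± 0.00333 and 0.427 ± 0.137. The matricellular protein gene CYR61 (CCN1), the Wnt inhibitor gene DKK1 and the keratin genes KRT7, KRT80 and KRT81 fell as well, while HAS3, a hyaluronan synthase, and the chromatin factor gene HMGA2 rose. As groups, DNA replication genes stood lower with both shRNAs, cholesterol genes lower with shRNA 1 and hypoxia genes higher with shRNA 2. None of these lists was called with an estimated correlation.

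In the planned limma fit 2815 of 16239 genes passed with the same sign for both shRNAs, 1553 up and 1262 down, 229 and 156 of them by a log2 fold change of at least 1. With each shRNA alone 3222 (1518 up, 1704 down) and 3055 genes (1800 up, 1255 down) passed, and 1150 passed with both in the same direction, 658 up and 492 down, where independent lists would share 168 and 132. Another 153 passed with opposite signs (independent lists 306). The covariance of the fold changes of both shRNAs was 0.116 across genes, against 0.0345 for simulated unchanged groups with the same controls, and the correlation 0.447 against 0.501. With each shRNA set against a different one of the 2 control libraries, a split added after the data were seen, the covariance was 0.0726 and 0.0775. A deviation common to both control libraries would remain in these values, so part of the excess may still come from the controls. The knockdown count was 686 and 748 without the first or second 20 mM control library, and 1808 without the filter on low values.

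Among the largest falls, with log2 fold changes over both shRNAs, were SLC2A3 (−2.97, SE 0.10, limma adjusted p = 8.5e-05), NGFR (−2.95), KRT80 (−2.43, 20.1 FPKM in controls against 2.49 and 3.38 with shRNA 1 and 2), CYR61 (−2.35, 42.9 against 6.00 and 9.63), the hair keratin-associated gene KRTAP3-1 (−2.35, 6.46 against 0.846 and 0.116), DKK1 (−2.21, 277 against 39.99 and 86.8), KRT81 (−2.21, 9.45 against 0.592 and 2.26) and KRT7 (−2.18, 40.8 against 12.2 and 5.46). HMGN2, a nucleosome-binding protein gene with 36 annotated copies that could share reads, went from 143 to 91.3 with shRNA 1 and to 11.1 with shRNA 2 (−2.10). The largest rises were PKIB, an inhibitor of protein kinase A (2.25, SE 0.11, limma adjusted p = 1.9e-04, 2.51 against 12.9 and 18.8), HAS3 (2.18, 10.04 against 29.3 and 81.5), the epithelial transcription factor EHF (2.09, 3.19 against 12.4 and 23.3), the telomere CST component STN1 (1.99, 14.9 against 64.5 and 59.6), HMGA2 (1.95, 13.8 against 52.6 and 59.5), the ATP synthase subunit ATP5MC1 (1.89, 9.39 against 45.8 and 31.2) and MT1E (1.89, 77.1 against 179 and 472). TRNP1 (1.86), the monoamine oxidase MAOB (1.86) and TMEM158 (1.81) followed. The related kinase gene MAPKAPK3 rose (0.39, adjusted p = 0.0203, 24.0 against 29.6 and 33.9), while MAPK14 (0.09), HSPB1 (−0.15), ZFP36 (−0.26), DDIT3 (0.06), HSPA5 (0.04) and ASNS (−0.21) did not pass. The mean for HSPA5 hides opposite changes, since in the read-based fit it fell with shRNA 1 and rose with shRNA 2. MAPK14, HSPB1, ZFP36 and ASNS also differed between the shRNAs (shRNA 2 minus shRNA 1 of 0.68, 0.63, 0.45 and −0.83). ARRDC4 was at 6.06 FPKM with shRNA 1 and 1.58 with shRNA 2 against 1.72 in controls, so its shRNAs had opposite signs.

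In all, limma camera called 9 of 32 lists for the knockdown, 2 up and 7 down, and 0 with an estimated correlation. Of the 42 DNA replication genes 33 fell and 1 rose over all genes, and 34 fell and 1 rose when adjusted over the list alone (median −0.57, limma camera adjusted p = 2.1e-13, adjusted p = 0.0630 with an estimated correlation). CDC6, which loads the replicative helicase, went from 28.5 FPKM to 9.73 and 11.7, UHRF1, which maintains DNA methylation, from 52.8 to 15.9 and 27.6, TYMS, thymidylate synthase, from 27.1 to 6.45 and 18.8, and E2F2 from 8.90 to 3.85 and 3.09. Of 22 hypoxia genes 12 rose and 0 fell, or 16 and 1 when adjusted over the list alone (median 0.68, limma camera adjusted p = 2.9e-08, adjusted p = 0.302 with an estimated correlation). AK4 went from 5.68 to 18.4 and 20.53 FPKM and INSIG2 from 3.29 to 7.50 and 9.96, while NDRG1 went from 11.96 to 15.6 and 107 and the mitophagy receptor BNIP3L from 8.46 to 13.6 and 38.9. The hypoxia list was not called with shRNA 1 alone (median 0.14, limma camera adjusted p = 0.262) and was with shRNA 2 (1.19, 5.0e-14, adjusted p = 0.209 with an estimated correlation). Of 26 cholesterol genes 9 fell and 0 rose, or 16 and 1 when adjusted over the list alone (median −0.41, limma camera adjusted p = 2.4e-05, adjusted p = 0.177 with an estimated correlation), among them the regulator SREBF2 (35.5 to 16.04 and 16.3 FPKM), HMGCS1 (27.6 to 13.6 and 13.6) and SQLE (24.2 to 10.8 and 14.1). The fall of the list was in shRNA 1, with 19 down and 0 up (median −0.70, limma camera adjusted p = 8.0e-10, adjusted p = 0.0547 with an estimated correlation). In cells with shRNA 2, 3 fell and 2 rose (−0.05, adjusted p = 0.560).

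Of 39 ATF4 genes 14 fell and 3 rose, or 15 and 4 when adjusted over the list alone (median −0.18, limma camera adjusted p = 0.00483, adjusted p = 0.310 with an estimated correlation). ATF3 had a log2 fold change of −1.47, CHAC1 of −0.98, PHGDH of −0.83 and AARS of −0.55. With shRNA 2 alone limma camera called the list (−0.26, adjusted p = 0.282 with an estimated correlation). With shRNA 1 it did not (−0.15, adjusted p = 0.186), while fry did (adjusted p = 0.0113). Of 20 YAP and SRF targets 8 fell and 2 rose, or 10 and 2 when adjusted over the list alone (median −0.23, limma camera adjusted p = 0.00543, adjusted p = 0.483 with an estimated correlation). Besides CYR61 these were AMOTL2 (28.1 to 6.59 and 7.42 FPKM), CTGF (4.88 to 0.504 and 1.01) and AJUBA (20.2 to 7.35 and 6.70). In cells with shRNA 1, 13 fell and 0 rose (median −0.58, limma camera adjusted p = 2.5e-05, adjusted p = 0.304 with an estimated correlation). In cells with shRNA 2, 5 fell and 4 rose (−0.07, adjusted p = 0.328). In the mitosis list of 35, 5 fell, among them KIF2C (−0.70), HMMR (−0.81) and CENPA (−0.67), and CDC25B rose (0.58), against 11 and 1 when adjusted over the list alone (median −0.22, limma camera adjusted p = 0.00164, adjusted p = 0.531 with an estimated correlation). This came from shRNA 1, with 20 down and 1 up (median −0.55, limma camera adjusted p = 2.8e-09, adjusted p = 0.304 with an estimated correlation). In cells with shRNA 2, 5 rose and 2 fell (0.08, adjusted p = 0.378).

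The ribosomal protein list was called down with 3 of 35 members down, RPL8 (−0.95) and EEF2 (−0.36) among them, and 0 when adjusted over the list alone (median −0.22, limma camera adjusted p = 0.00273, adjusted p = 0.708 with an estimated correlation). EEF2 encodes a translation elongation factor, so the list does not hold ribosomal proteins only. Fry did not call this list (fry adjusted p = 0.267). In the ribosome biogenesis list NOLC1 (−0.74) and GRWD1 (−0.39) were among 4 that fell and MYC (0.59) was the 1 that rose, against 6 and 1 when adjusted over the list alone (28 tested, median −0.15, limma camera adjusted p = 0.0225, adjusted p = 0.302 with an estimated correlation). Autophagy and lysosome genes were called up with 7 of 40 up and 0 down, or 10 and 2 when adjusted over the list alone. The proton pump subunits ATP6V1A (1.16) and ATP6V0D1 (0.55), the protease CTSB (0.95) and ATG16L1 (0.46) rose (median 0.15, limma camera adjusted p = 0.0498, adjusted p = 0.545 with an estimated correlation). The autophagy call held in 3 of 8 fits with a library left out and the ribosomal protein and ribosome biogenesis calls in 6 and 7, with ribosomal medians of −0.36 to −0.12. The autophagy and ribosome biogenesis calls were lost under quantile normalization (both adjusted p = 0.0552). For each shRNA alone, limma camera called ribosomal proteins with shRNA 1 (median −0.37, adjusted p = 0.664 with an estimated correlation) and not with shRNA 2 (−0.09). Under quantile normalization it called them with shRNA 2 (−0.21) and not with shRNA 1 (−0.14). It called ribosome biogenesis and autophagy with shRNA 2 (−0.22 and 0.20, adjusted p = 0.209 and 0.458 with an estimated correlation) and not with shRNA 1 (−0.06 and 0.11). The difference between the shRNAs was not called for ribosome biogenesis (adjusted p = 0.0593). Mitochondrially encoded genes held 11 of 13 members above 0 with 1 past the test (median 0.34, or 0.05 under quantile normalization, limma camera adjusted p = 0.0579, and 0.0113 on recovered reads), and their share of reads was 11.1% and 9.62% with shRNA 1 and 7.06% and 9.10% with shRNA 2, against 6.83% and 7.82% in the controls.

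The lists closest to MK2 itself were not called by limma camera for the knockdown. The p38 and MK2 pathway list, which holds MAPKAPK2, was called by fry (adjusted p = 0.0147) but not without MAPKAPK2 (adjusted p = 0.396), in a test added after the data were seen. With shRNA 2 alone fry called the list without MAPKAPK2 up (median 0.18, fry adjusted p = 0.0192), while limma camera did not (adjusted p = 0.209). With shRNA 1 alone fry did not call it (median −0.04, adjusted p = 0.107). Of 23 genes of the p38 and MK2 pathway 3 rose and 4 fell, or 5 and 5 when adjusted over the list alone (median 0.09, mean −0.07, limma camera adjusted p = 0.939), with the kinase MAP3K5 (ASK1) up (2.93 to 7.66 and 7.20 FPKM) and RPS6KA5 (MSK1) down (2.22 to 0.862 and 0.550). Of 20 mRNAs with AU-rich elements or TTP control, 5 rose and 2 fell, or 6 and 5 when adjusted over the list alone (limma camera adjusted p = 0.716). With shRNA 2 alone fry called these mRNAs (median 0.28, fry adjusted p = 0.0132) and limma camera did not (adjusted p = 0.147). With shRNA 1 alone fry did not (median −0.08, adjusted p = 0.105). The protease PLAU rose (6.70 to 48.2 and 11.4 FPKM), as did MYC (112 to 175 and 164), and IER3 (338 to 155 and 212) and HMOX1 (12.2 to 7.06 and 3.26) fell. Of 32 immediate-early genes 8 rose and 7 fell, or 11 and 12 when adjusted over the list alone (limma camera adjusted p = 0.560). With shRNA 1 alone that list was called down, with 15 down and 7 up (median −0.48, limma camera adjusted p = 0.0410, adjusted p = 0.542 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.116).

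**Figure D3:**
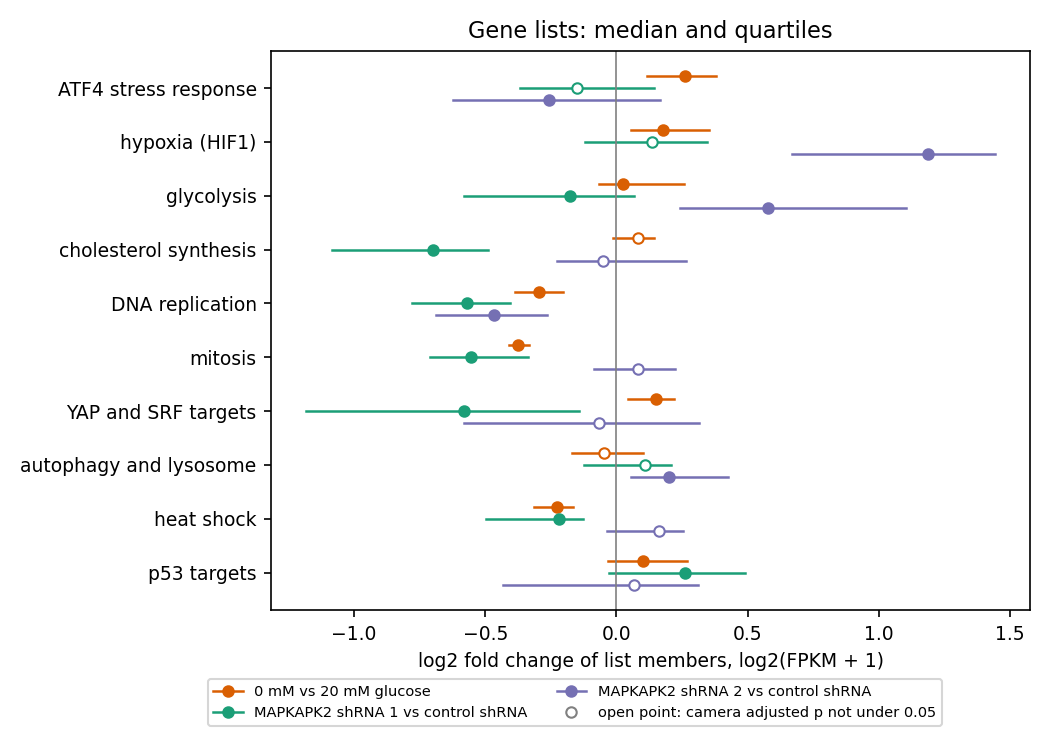
Median (points) and quartiles (lines) of the log2 fold changes of the members of 10 gene lists (horizontal axis) for glucose withdrawal and each MAPKAPK2 shRNA against control at 20 mM, with filled points where the limma camera adjusted p with the preset correlation is under 0.05. DNA replication genes lie below 0 in all 3 comparisons (−0.29, −0.57 and −0.47), and the hypoxia list has its highest median, 1.19, with shRNA 2.

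Glucose withdrawal and MAPKAPK2 knockdown were then set side by side. The planned fit gave 0 genes past the threshold in both, since limma called 0 for glucose. In the read-based fit, added after the data were seen, 8 genes rose in both (independent lists 2.96), 2 fell in both (0.327), 5 rose at 0 mM and fell with the shRNAs (2.72) and 0 did the opposite (0.355). DDIT4, MT1E, LAMB3, AHNAK2, HERPUD1, HK2 and NDRG1 rose in both, with planned-fit knockdown log2 fold changes of 1.08, 1.89, 0.98, 0.70, 0.63, 0.75 and 1.70. DHRS2 and GMNN fell in both (knockdown −1.40 and −0.39). Of these, HK2 and NDRG1 passed with shRNA 2 and not with shRNA 1 alone, and GMNN with shRNA 1 and not with shRNA 2 alone. The 8th riser was GTF2IP1, a pseudogene whose reads may come from near-identical genes. SLC2A3, KRT80, KRT7, PCK2 and IRS2 rose at 0 mM and fell with the shRNAs (knockdown −2.97, −2.43, −2.18, −0.67 and −0.74), IRS2 past the test with shRNA 1 and not with shRNA 2 alone. The covariance of the fold changes was 0.0436 across genes, against 0.0345 for simulated unchanged groups with the same controls, and the correlation 0.311 against 0.578. Here too the lower correlation does not mean agreement below chance. With a different control library for each comparison, a split added after the data were seen, the covariance was 0.00486 and 8.2e-04. The correlation was then 0.0266 and 0.00452. Each comparison then has 1 library at 20 mM with control shRNA, and part or all of the excess may come from the shared controls.

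The 2 shRNAs also differed from each other. With shRNA 2 the cells had far more mRNA of ANGPTL4, a lipase inhibitor gene (32.8 FPKM ± 11.6 against 1.27 ± 0.219 with shRNA 1, SD, n = 2 each), of NDRG1 (107 ± 19.8 against 15.6 ± 0.192) and of the aldolase gene ALDOC (19.4 ± 4.70 against 2.25 ± 0.250). With shRNA 1 they had more HMGN2 (91.3 ± 7.84 against 11.1 ± 0.447), more of the granin gene SCG2 (58.4 ± 2.47 against 9.19 ± 1.62) and more of the helix-loop-helix inhibitor ID3 (93.8 ± 11.1 against 16.7 ± 2.62). Glycolysis, hypoxia, mitosis and lipid synthesis genes stood higher with shRNA 2. None of these lists was called with an estimated correlation.

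By limma 3602 genes differed, 2119 higher with shRNA 2 and 1483 higher with shRNA 1. The log2 fold change of shRNA 2 over shRNA 1 was 3.86 for ANGPTL4 (SE 0.24, limma adjusted p = 3.3e-04), 2.69 for NDRG1, 2.67 for the ubiquitin ligase RNF128, 2.63 for ALDOC and 2.56 for the arginase ARG2. It was −2.93 for HMGN2, −2.55 for SCG2, −2.42 for ID3, −2.34 for MSH4 and −2.29 for KRT13. The split of 58.8% higher with shRNA 2 became 49.2% under quantile normalization.

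Of 27 glycolysis genes 21 were higher with shRNA 2 and 0 lower, or 22 and 0 when adjusted over the list alone (median 0.80, limma camera adjusted p = 4.1e-10, adjusted p = 0.218 with an estimated correlation). LDHA was at 108 FPKM with shRNA 1, 314 with shRNA 2 and 123 in controls, ENO2 at 6.38, 23.3 and 10.3, and HK2 at 9.03, 21.8 and 8.03. Against the controls 17 glycolysis genes rose and 3 fell with shRNA 2 (median 0.58, limma camera adjusted p = 4.9e-05, adjusted p = 0.491 with an estimated correlation). In cells with shRNA 1, 1 rose and 9 fell (median −0.18, limma camera adjusted p = 0.0139, adjusted p = 0.648 with an estimated correlation). That call was lost under quantile normalization (−0.01, adjusted p = 0.174). Of 22 hypoxia genes 16 were higher and 0 lower, or 18 and 0 when adjusted over the list alone (median 1.00, limma camera adjusted p = 4.1e-10, adjusted p = 0.218 with an estimated correlation), with BNIP3 at 6.11, 29.9 and 7.22. Against the controls 16 hypoxia genes rose with shRNA 2 (median 1.19), and 4 rose and 3 fell with shRNA 1 (median 0.14, not called). Of 35 mitosis genes 23 were higher and 1 lower, or 29 and 1 when adjusted over the list alone (median 0.57, limma camera adjusted p = 1.3e-09, adjusted p = 0.218 with an estimated correlation), with UBE2C at 57.0, 133 and 94.0, CCNA2 at 25.3, 52.0 and 44.4, AURKA at 16.1, 32.7 and 23.2 and CENPA at 4.91, 12.7 and 13.3.

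Cholesterol genes (15 of 26 higher, 0 lower, or 18 and 0 when adjusted over the list alone) and fatty acid synthesis genes (8 of 15 higher, 0 lower, or 9 and 0) had medians of 0.58 and 0.48. The limma camera adjusted p was 2.9e-07 and 1.3e-05, and adjusted p = 0.208 and 0.218 with an estimated correlation. INSIG1 and STARD4 were higher with shRNA 2 by 1.89 and 1.92. The desaturases SCD and FADS1 and the phosphatidate phosphatase LPIN1 were higher by 2.26, 1.45 and 1.54. Heat shock genes were called up as well (12 of 21 higher, 1 lower, or 15 and 1 when adjusted over the list alone, median 0.41, adjusted p = 0.218 with an estimated correlation). The call was lost under quantile normalization (median 0.15, adjusted p = 0.0722). Epithelial genes were lower with shRNA 2 (10 of 18, 1 higher, or 11 and 2 when adjusted over the list alone, median −0.50, limma camera adjusted p = 8.0e-04, adjusted p = 0.238 with an estimated correlation), with CDH1, E-cadherin, at −1.34 and EPCAM at −0.95. Histone genes (median 0.78), immediate-early genes (0.46), YAP and SRF targets (0.34), nucleotide sugar and pentose phosphate genes (0.30), TCA and gluconeogenesis genes (0.28), ER chaperones (0.28), nuclear genes of oxidative phosphorylation (0.27), ribosomal proteins (0.23), BCL2 family genes (0.18) and autophagy genes (0.15) were also called higher with shRNA 2. Nuclear-retained long RNAs (−0.31), p53 targets (−0.27) and ATF4 genes (−0.17) were called lower. In all, 20 of 32 lists were called, 16 higher with shRNA 2 and 4 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.208. With the replicate number as a block the calls of BCL2 family genes, autophagy genes and nuclear-retained RNAs were lost (adjusted p = 0.0509, 0.0508 and 0.0622). They held in 2, 5 and 5 of 8 fits with a library left out. The ER chaperone call held in 5, those of oxidative phosphorylation and ribosomal proteins in 6 and that of ATF4 genes in 7. Without 1 library the medians ran from 0.13 to 0.44 for oxidative phosphorylation and from 0.06 to 0.44 for ribosomal proteins, and were as low as 0.50 for histone and 0.09 for autophagy genes. Under quantile normalization the calls of pentose phosphate genes (median 0.15), ER chaperones (0.18), oxidative phosphorylation (0.10), ribosomal proteins (−0.08), BCL2 family genes (0.08) and autophagy genes (0.08) were lost. Those of BCL2 family and autophagy genes were lost under median ratio rescaling as well. Quantile normalization also moved the medians of fatty acid synthesis genes (0.27), TCA and gluconeogenesis genes (0.17), YAP and SRF targets (0.16), epithelial genes (−0.76), p53 targets (−0.41) and ATF4 genes (−0.37). Ribosome biogenesis was called lower there (−0.29), under median ratio rescaling (−0.12) and on recovered reads (−0.09).

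**Figure D4:**
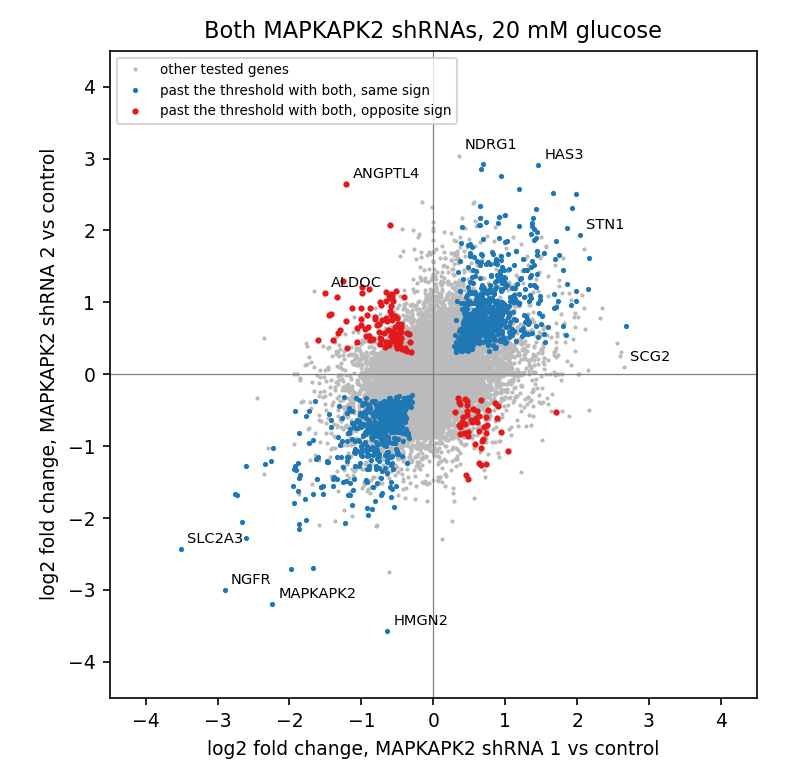
Log2 fold change against control at 20 mM with MAPKAPK2 shRNA 1 (horizontal axis) and shRNA 2 (vertical axis) for the 16239 tested genes, one point per gene. Blue points are the 1150 genes past the limma threshold with both shRNAs in one direction and red points the 153 with opposite signs; MAPKAPK2 lies at −2.24 and −3.20.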

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

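The tests of scaling and of the HMGN2 copies were written before their results were seen; the other tests in this part were chosen after, and the bound for the hypoxia test was made stricter once its value was known.

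The test of shRNA 2 against shRNA 1 was past its threshold for 42 of the 76 genes named for the knockdown, 30 higher with shRNA 2 and 12 higher with shRNA 1. The log2 differences (shRNA 2 minus shRNA 1) of the genes higher with shRNA 2 were 2.69 for NDRG1, 2.24 for TMEM158, 1.81 for MAOB, 1.45 for HAS3 and for BNIP3L, 1.40 for TYMS, 1.39 for MT1E, 1.202 for CENPA, 1.19 for HK2, 1.10 for DKK1, 1.09 for SLC2A3, 1.06 for KRT81, 1.04 for IRS2 and 1.00 for HMMR. They were 0.87 for TRNP1, 0.86 for EHF, 0.83 for HSPA5, 0.79 for IRF7, 0.76 for UHRF1, 0.68 for MAPK14, 0.63 for HSPB1, 0.61 for CYR61, 0.59 for AARS, 0.52 for AHNAK2, for EEF2 and for PKIB, 0.45 for IER3 and for ZFP36, 0.40 for GMNN and 0.33 for KRT80. Those higher with shRNA 1 were ATP5MC1 at −0.56, ATF3 at −0.68, ATP6V1A at −0.71, ASNS at −0.83, HMOX1 at −0.93, MAPKAPK2 at −0.95, KRT7 at −1.03, CHAC1 at −1.199, PHGDH at −1.33, ARRDC4 at −1.45, PLAU at −2.00 and HMGN2 at −2.93. Among the lists called for the knockdown, together with glycolysis, those called between the shRNAs had medians of 1.00 for hypoxia, 0.80 for glycolysis, 0.58 for cholesterol, 0.57 for mitosis, 0.34 for YAP and SRF targets, 0.23 for ribosomal proteins, 0.15 for autophagy and −0.17 for ATF4. None of these was called with an estimated correlation. The ribosomal protein and autophagy calls were lost under quantile normalization, with medians of −0.08 and 0.08.

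Glycolysis and hypoxia genes stood higher with shRNA 2 than with shRNA 1. Scaling between libraries is argued against as the whole cause by quantile normalization. Under it the medians were 0.59 for glycolysis (0.80 as reported) and 0.95 for hypoxia. Median ratio rescaling used factors of 0.992 to 1.03 per library, so it could change little and adds little here. Neither scaling could show a shift common to most genes. For glycolysis, a response that grows in one direction with the loss of MAPKAPK2 is not settled. The median with shRNA 1 was −0.18 with 9 members down and 1 up. That call was lost with an estimated correlation (limma camera adjusted p = 0.648) and under quantile normalization (median −0.01, limma camera adjusted p = 0.174). Members that fell with shRNA 1 and rose with shRNA 2 argue against such a response for those genes only. There were 4 in the planned fit and 3 under quantile normalization. For hypoxia, with a median of 0.14 with shRNA 1 and 4 members up and 3 down, such a response cannot be told apart from other explanations, since members went both ways. A state of the shRNA 2 cultures (such as density or oxygen) or another target of that shRNA may account for the 16 hypoxia genes that rose with it; with 1 set of cultures per shRNA these cannot be told apart.

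DNA replication genes stood lower both at 0 mM glucose and with MAPKAPK2 shRNA, and both comparisons use the same 20 mM controls. For the knockdown, high values in those controls are argued against as the whole cause: against the 0 mM controls the median was still −0.28, with 18 members down and 3 up (limma camera adjusted p = 1.0e-04), and −0.26 to −0.24 with one 0 mM library left out. Scaling is argued against too, with the same limits, by quantile normalization. Under it the smallest ratio of the median to the reported one was 0.870 over both comparisons. At 0 mM glucose the highest median with one 20 mM control left out was −0.26, but no other 20 mM control libraries were analysed here, so a slower cell cycle without glucose and high values in both controls cannot be told apart.

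HMGN2 was lower with shRNA 2 than in any other group. Reads moving to its copies are argued against, since HMGN2 summed with its 36 annotated copies was at 8.19% of the 20 mM controls. A single odd library is argued against as well, since the higher of both shRNA 2 libraries was at 13.3% of the lowest library of the other groups. Another target of shRNA 2 may account for the log2 difference of −2.93, but with a single shRNA of that sequence it cannot be told apart from a response to the deeper loss of MAPKAPK2.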

How the results depend on the processing

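Protein-coding genes only, recovered reads and all settings of the read-based glucose fit were chosen after the data were seen. Over 11 results, 90 of 107 alternatives and 62 of 88 fits without one library stayed within 1.5 times of the count or, for the MAPKAPK2 level, kept direction and call. A count that stayed at 0, as for glucose and the genes shared in many fits, was taken as unchanged. The shared count must be 0 where the glucose count is 0. For lists only their number was compared. These shares therefore overstate how stable the gene counts above 0 were. The larger direction within a count turned for shRNA 1 (1518 up and 1704 down) under median ratio rescaling (1608 and 1589) and without the second 20 mM control (510 and 499), and between shRNAs (2119 and 1483) under quantile normalization (1768 and 1822). The MAPKAPK2 log2 fold change was −3.40 to −2.70 over the alternatives (limma adjusted p 5.2e-09 to 0.00365). With no filter on low values the counts were 6 for glucose, 1808 for the knockdown, 751 for both shRNAs and 4 shared by glucose and knockdown. Without a trend in eBayes they were 2 for glucose and 1 shared, on recovered reads 28 and 15, and on protein-coding genes, with fewer genes tested, 8 and 4. With only the groups compared, and so fewer residual degrees of freedom, they were 961 for shRNA 2, 504 for both shRNAs and 1136 between shRNAs. With an estimated correlation 2 glucose and 0 knockdown lists were called. The read-based glucose count became 158 on the 4 control libraries alone, among them all 28. Where no construction shows it, the cause was not tested.

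Without 1 library the lone one of its group is assumed to vary like the others. The counts were then 0 to 1 for glucose and for the genes shared, 686 to 3437 for the knockdown, 942 to 4054 for shRNA 1, 1015 to 3026 for shRNA 2, 299 to 1324 for both shRNAs and 1335 to 3473 between shRNAs, and 11 to 14 glucose and 7 to 11 knockdown lists were called. MAPKAPK2 stayed at −2.75 to −2.68. Leaving out the first or second 20 mM control gave 686 or 748 for the knockdown, 942 or 1009 for shRNA 1, 1015 or 1152 for shRNA 2 and 299 or 331 for both. Leaving out the first or second shRNA 1 library gave 1514 or 1610, 998 or 1057 (shRNA 1), 436 or 444 (both) and 1384 or 1335 (between shRNAs). The single glucose call came without the second shRNA 2 library. The read-based glucose count ran from 0, without either 20 mM control, to 196, without the first shRNA 2 library, with 6 or 1 without a 0 mM control, 7 without either shRNA 1 library and 194 without the second shRNA 2 library.

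Of the 70 named knockdown genes called, some lost the call in a fit without one library and 7 in another setting. With only the groups compared, a setting counted apart, 3 lost the call. Of 40 named glucose genes 21 gained one in another setting. These settings include the recovered reads, by which the glucose genes were named, so the gains lend those genes no separate support. All 28 between shRNAs kept theirs.

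Deviations of samples with the same replicate number had correlations of −0.03 to 0.18 over 6 pairs of groups, so the numbers do not pair the samples throughout. The highest was between the 0 mM controls and shRNA 2, so a factor shared by replicate number in some groups stays open. The fit with the replicate block called 0 genes for glucose, 3018 for the knockdown (1627 up, 1391 down) and 3806 between shRNAs; the read-based glucose count became 80, with all 28 among them.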

Other observations

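The list tests in this part were planned; the metallothionein and keratin groups were chosen after their values were seen.

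Of 27 tested p53 targets 9 were lower and 2 higher with shRNA 2 than with shRNA 1, or 11 and 2 when adjusted over the list alone (median −0.27, limma camera adjusted p = 9.6e-04, adjusted p = 0.218 with an estimated correlation). The cytokine gene GDF15, which is also a target of ATF4, was at 98.5 FPKM with shRNA 1 and 25.1 with shRNA 2 against 70.2 in controls, and the sestrin SESN1 at 8.24 and 2.85 against 4.05. With shRNA 1 alone p53 targets were called up (8 rose, 3 fell, median 0.26, limma camera adjusted p = 0.0329, adjusted p = 0.304 with an estimated correlation).

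Of 24 tested interferon-stimulated genes 6 fell and 1 rose over both shRNAs, or 6 and 2 when adjusted over the list alone, and the list was not called by limma camera (adjusted p = 0.101) but was by fry (adjusted p = 0.00107). IFI6 had a log2 fold change of −1.90, the transcription factor IRF7 of −1.03 and OAS3 of −0.64. For the knockdown fry also called lists of mesenchymal (median 0.69, fry adjusted p = 0.00107) and MondoA genes (0.36, 0.00214) that limma camera did not. The same held for pentose phosphate (0.05, 0.00241), NRF2 antioxidant (−0.10, 0.00705) and Wnt target genes (−0.12, 0.00705). Of 4 tested metallothioneins, metal-binding stress proteins on chromosome 16, MT1E and MT2A rose with the shRNAs, and 3 rose on recovered reads. MT2A was at 199 FPKM in the 20 mM controls, 346 at 0 mM, 271 with shRNA 1 and 626 with shRNA 2 (knockdown log2 fold change 1.045). Of 7 tested keratin genes on chromosome 12, KRT7, KRT18, KRT80 and KRT81 fell with the shRNAs, and 0 rose; under quantile normalization 3 fell, and on recovered reads 5 fell and 1 rose, with a median of −1.19 against −0.39. KRT18 was at 293 FPKM in controls, 268 with shRNA 1 and 190 with shRNA 2, so its fall was small (−0.38).

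TXNIP had 0 reads in the control and shRNA 1 libraries and 2 and 5 reads in the shRNA 2 libraries. Of the lists of other cell types, 1 of 10 fibroblast genes was tested, COL1A1 (highest library 6.72 FPKM), and 0 of 12 blood and endothelial genes, of which CD14 was highest at 0.648 FPKM.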
